A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

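RNA abundance was measured in yeast, Saccharomyces cerevisiae strain S288C, grown at 28 °C in synthetic SD medium and then moved to 37 °C (heat), moved to 10 °C (cold) or left at 28 °C (control). Each of the 3 temperature series was sampled at 8 times, 0, 15, 30 and 60 min and 2, 4, 8 and 24 h, with 1 array per temperature and time, 24 arrays in all. Per the labels' protocols, total RNA was extracted with a commercial yeast kit and cleaned on columns. The labelled RNA of the control and cold samples was made with an Ambion amplification kit. The heat samples went through a Roche target amplification kit combined with the Ambion transcription step. Amplification method and heat series therefore coincide completely.

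The values are on a log2 scale and were deposited by the authors as 1 value per probe set and array. They were summarised with RMA, per the submitters' processing notes. The RMA version and whether all 24 arrays were processed together are not given in the sources used here. No scanner files were used here. The deposited log2 values ran from 3.49 to 15.1, and no further normalization was applied. RMA makes the brightness distributions of arrays alike, so a shift of total RNA per cell cannot be seen. It also compresses differences of dim probe sets, so a change of a gene near background is understated.

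The 1-colour array carries 10928 probe sets. In the platform annotation 5498 of these have 1 S. cerevisiae gene, 1 has several genes, and 1746 belong to other species. The remaining 3683 are not listed there and are unnamed here. Among the named probe sets, 103 carry the suffix for several transcripts and 25 the suffix for cross-hybridisation, so their genes are less certain. Values of the 47 genes with more than 1 probe set were averaged, which left 5449 genes for testing. Gene symbols came from the annotation and from a RefSeq gene table of assembly R64, which was used for names and coding lengths alone. The median log2 level was 10.75 for S. cerevisiae probe sets and 5.09 for those of other species, which serve as a background reference. The 95th percentile of the mean level of the other-species probe sets was 6.53, and 177 genes had a mean below it. The number of arrays limits the precision.

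No time point was repeated. The arrays of a time window stand in for replicates, so the tests measure the spread between times around window means. P-values do not cover differences between independent cultures. In the fit of all 24 arrays each gene has 1 such spread, shared by the 3 series and both windows. Arrays outside a window therefore also enter its p-values. The early window held the 3 arrays at 15, 30 and 60 min and the late window the 4 arrays at 2, 4, 8 and 24 h. Models were fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0) by lmFit and eBayes to all 24 arrays, with time point as a block and a term for heat and for cold in each window. Residual degrees of freedom were 10 and prior degrees of freedom 3.56. In the comparisons named heat early, heat late, cold early and cold late, a value is the difference from the time-matched control minus the same difference at 0 min. Heat against cold sets these values against each other. The comparisons named heat late against early and cold late against early do not use the 0 min arrays. A separate fit of the 8 control arrays compared 2 to 24 h with 0 to 60 min. P-values were adjusted by the Benjamini-Hochberg method over all 5449 genes, with a threshold of 0.05. The subtraction of the 0 min difference rests on a single array per series, which widens the errors of the comparisons that use it.

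Gene lists numbered 31 and were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in 1 direction, were run beside it. No list passed with an estimated correlation in any of the comparisons. Median standard errors over genes were 0.49 for the early comparisons, 0.48 for the late ones, 0.32 for late against early and 0.22 within the control series.

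The designs, the lists, the processing alternatives and the rule for named genes were fixed before the data were examined. For heat early, heat late, cold early and cold late, the rule takes the 5 highest and 5 lowest changes among genes past the threshold with 1 sign at every time of the window, and the 2 members with the smallest p from each list that passes. The other comparisons take the 3 highest and 3 lowest. Where fewer genes pass, those with the smallest p fill the places and are given as not past the threshold. HSP104, HSP26, SSA4, HSP12, CTT1, TPS1, TIP1, TIR1, NSR1 and OLE1 are reported in any case. Probe sets with several genes, without a name or of another species are not named, and 1 gene that the rule takes in heat early is not reported here.

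The fits were tested on simulated data in which 200 of the 5449 genes were changed. In heat early, 0% of the genes changed by 1 on the log2 scale were recovered, 47.5% of those changed by 2 and 92% of those changed by 4. The corresponding shares were 0%, 53.5% and 92% in heat late, 0%, 52% and 96.5% in cold early, and 0%, 51% and 94% in cold late. They were 24.5%, 84% and 98% in heat late against early and 22.5%, 80% and 98% in cold late against early. A list test on simulated data for heat early passed the 2 shifted lists and 0 of the 29 others. The simulated noise was independent between genes, so this does not show how the list test behaves where genes of a list move together.

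Alternatives covered the 0 min baseline, the time block, narrower windows, fits of 2 series alone, leaving out each time point, array weights, a filter on dim probe sets, renewed quantile normalization, median centring, the brightest probe set per gene, a variance trend with a robust prior, and a spline of time. Fits of the early arrays alone and of an early pulse were added after the data had been seen. Renewed quantile normalization moved array medians by at most 0.046 and median centring by at most 0.058 on the log2 scale. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.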

Results

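Transcript levels of 5449 yeast genes were followed in 3 cultures of strain S288C, a laboratory strain of baker's yeast, after a shift from 28 °C to 37 °C, a shift to 10 °C, or no shift. Each series comprised 8 arrays, taken between 0 min and 24 h. The series addresses how the transcriptome changes over time as yeast adapts to heat and to cold. Values are log2 RMA levels as the authors deposited them, and changes are given on the log2 scale with the standard error of the fit. The early window pools 3 arrays per series (15 to 60 min) and the late window 4 arrays (2 to 24 h). The array medians of the yeast probe sets lay close together, near 10.75.

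At 0 min the cold and control cultures had nearly the same profile, whereas the heat series stood far from both. Across genes the cold array correlated with the control array at r = 0.990, and 30 genes (0.55%) differed by at least 2-fold. This small cold difference was not random, since it correlated across genes with that at 15 min (r = 0.656), though not at 24 h (0.020). Ribosome biogenesis (median 0.36) and general stress genes (-0.26) already differed in the direction of their early cold changes. Subtracting the 0 min difference makes those early values smaller, and its cause was not tested. The heat array correlated with the control array at r = 0.703, and 2397 genes (44.0%) differed by at least 2-fold. Cytosolic ribosomal protein genes were lower in the heat series at 0 min (median difference -1.47), as were oxidative phosphorylation genes (-1.92). Ribosome biogenesis genes were higher (median 1.07). The difference followed the coding length of the genes. Its median was -1.01 among the shortest genes and 0.62 among the longest, when genes were split into 5 bins, with a Spearman rho across genes of 0.394, against -0.015 for the cold array. Genes are not independent replicates, so no p-value is attached to these correlations. The heat samples were amplified with an additional kit. Early and late heat values are therefore given relative to the series' own 0 min array unless stated otherwise, while late against early sets the windows against each other without it. Either way an effect of the kit is removed only where it shifts a gene's log2 level by a constant, which cannot be settled here. Some probe sets lay in different signal ranges, as CDC33 did at 0 min (8.71 in heat, 13.5 in the control). The sizes of heat and heat against cold values carry this limit.

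**Figure D1:**
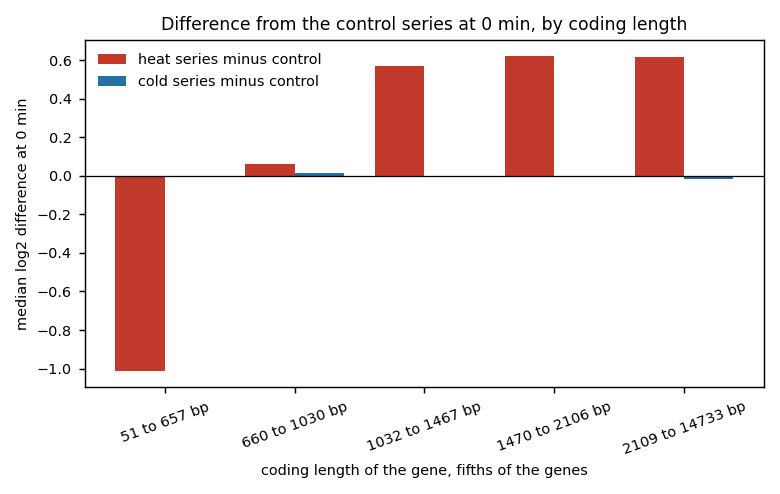
Bars give the median log2 difference from the control array at 0 min (vertical axis) for the genes split into 5 bins by coding length in bp (horizontal axis), for the heat array and the cold array. The heat bars run from -1.01 for the shortest genes to 0.62 for the longest, while the cold bars stay between -0.02 and 0.02.

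Measured from its own 0 min array, the heat culture moved fast and then part of the way back. At least 2-fold changes were counted for 408 genes at 15 min, 1055 at 30 min, 870 at 60 min, 347 at 2 h, 379 at 4 h and 588 at 8 h. The cold culture had lower counts than heat in the first hour and higher ones from 2 h to 8 h, with 263, 470, 550, 538, 833 and 1370 genes at the same times. In the control culture the number stayed between 0 and 31 up to 4 h and was 282 at 8 h. At 24 h it was 2225 in the control, 1840 in heat and 1467 in cold, so the control itself had moved far from its start. These counts come from single arrays, without a test.

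**Figure D2:**
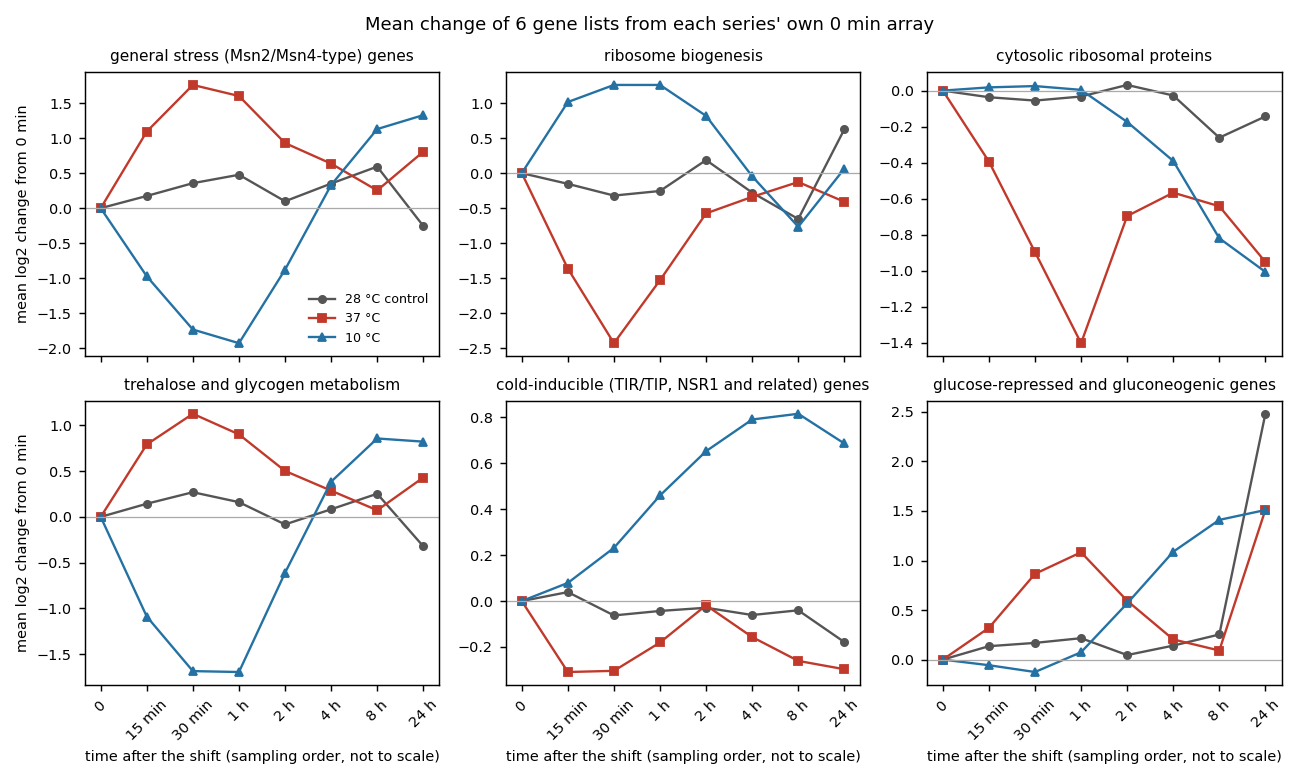
Each panel shows the mean log2 change of 1 gene list from the series' own 0 min array (vertical axis) at the 8 sampling times in order (horizontal axis), with 1 line per temperature and 1 array per point. General stress genes reach 1.76 in heat at 30 min and -1.93 in cold at 60 min, and ribosome biogenesis genes run the other way, to -2.43 in heat and 1.26 in cold.

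Within the first hour at 37 °C, genes for making ribosomes were lower and stress-defence genes were higher as groups, although no single gene passed the test. Of 95 ribosome biogenesis genes 94 had a negative early change, with a median of -1.52 (camera adjusted p = 1.8e-47 at the preset correlation, 0.46 with an estimated correlation). Of 127 cytosolic ribosomal protein genes 126 were negative, with a median of -0.88 (adjusted p = 3.2e-38, and 0.46 with an estimated correlation). All 41 general stress genes, the targets typical of the Msn2 and Msn4 activators, were positive, with a median of 1.12 (adjusted p = 7.8e-09, and 0.58 with an estimated correlation). Heat shock chaperones had a median of 0.57 with 30 of 32 positive (adjusted p = 3.8e-05, and 0.58 with an estimated correlation).

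At 30 min the mean of the ribosome biogenesis list stood at -2.43 and by 8 h at -0.13, close to its start. At 0 min this list had stood 1.07 above the control and the ribosomal protein list -1.47 from it. NSR1, a nucleolar protein of rRNA processing, had an early change of -2.78 ± 0.68 and stood at -4.01 on the 30 min array. NAN1, part of the complex that processes the small-subunit rRNA but not in the list, stood at -2.26 ± 0.58 with levels under the dim bound of 6.53 (4.48 to 4.62) at 15 to 60 min, NSA2, a factor of large-subunit assembly, at -1.91 ± 0.54, and GAR1, a protein of the pseudouridylation particle, at -1.52 ± 0.42. The ribosomal protein genes RPL21B and RPL1B had values of -1.17 ± 0.36 and -1.19 ± 0.41. The ribosomal protein list, unlike ribosome biogenesis, was lowest at 60 min (-1.40). CDC33, the cap-binding translation initiation factor, stood at -1.46 ± 0.35 and PRT1, another initiation factor, at -0.89 ± 0.43, in a list of 26 helicases and initiation factors that was lower with a median of -0.40 (adjusted p = 0.00011, and 0.58 with an estimated correlation).

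Among the stress genes the small heat shock protein HSP26 had an early heat change of 2.47 ± 1.79, the inducible chaperone SSA4 1.83 ± 0.81, the disaggregase HSP104 1.75 ± 1.02 and the membrane protein HSP12 1.18 ± 0.81. AHA1, a co-chaperone, stood at 0.90 ± 0.45, and the stress genes STF2 and DDR2 at 1.70 ± 0.65 and 1.74 ± 0.77. Trehalose and glycogen genes were higher as a group (median 0.83, 16 of 17 positive, adjusted p = 0.00023, and 0.58 with an estimated correlation), with 1.52 ± 0.64 for the trehalase NTH1, 1.16 ± 0.43 for the glycogen primer GLG1 and 0.71 ± 0.56 for the trehalose synthase TPS1. CTT1, the cytosolic catalase, had a change of 0.86 ± 1.53. The desaturase OLE1 stood at -0.56 ± 0.67, and the cell wall genes TIP1 and TIR1 at 0.08 ± 0.36 and 0.01 ± 0.38. The gene with the smallest p, AMA1, a meiotic activator of the anaphase-promoting complex, stood at 3.01 ± 0.53 (adjusted p = 0.37). It began at a log2 level of 6.1 on the heat 0 min array, under the 6.53 that bounds the dim genes. Among the 5 highest were also YGL258W-A (2.81 ± 0.78), YOR032W-A (2.59 ± 0.60) and BIM1, a microtubule-binding protein (2.07 ± 0.50), with adjusted p-values of 0.999, and these began under the dim bound too.

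Further lists were higher early in heat at the preset correlation. Stationary phase genes had a median of 1.44, with GAC1, a glycogen phosphatase subunit that began under the dim bound, at 2.73 ± 1.22 and SPG4 at 2.58 ± 1.18. Glucose-repressed genes stood at 0.60, with the acetate transporter ADY2 at 1.15 ± 0.61 and the acyl-CoA oxidase POX1 at 0.92 ± 0.48, and sulfur amino acid genes at 0.58, with SUL2 and MET28 at 1.46 ± 0.73 and 1.46 ± 0.75. Oxidative stress genes stood at 0.44, with the superoxide dismutase SOD2 at 1.46 ± 0.88 and the glutaredoxin GRX1 at 1.10 ± 0.59, and autophagy genes at 0.34, with ATG19 at 2.32 ± 0.95 and ATG31 at 0.84 ± 0.64. Oxidative phosphorylation genes were at 0.31, with QCR10 at 1.39 ± 0.69 and SDH4 at 1.29 ± 0.62, and mitochondrial ribosomal proteins at 0.30, with MRPL31 at 0.57 ± 0.39 and MRP17 at 0.43 ± 0.28. Proteasome genes were at 0.16, with their activator RPN4 at 1.18 ± 0.63 and PUP2 at 0.51 ± 0.32. ADY2, MET28, ATG19 and SDH4 began under the dim bound. Amino acid biosynthesis genes (median -0.45, with ARO4 at -1.21 ± 0.61 and PRO1 at -1.17 ± 0.60) and S phase genes (-0.52, with MSH6 at -0.92 ± 0.44 and the cohesin subunit SMC3 at -0.98 ± 0.53) were lower. Their adjusted p-values with an estimated correlation lay between 0.58 and 0.64. Altogether 11 lists were higher and 5 lower with camera, and fry passed 0.

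For single genes limma called 0 of 5449 in heat early, with 219 at an unadjusted p under 0.05. Adjusted over the list alone, 1 gene passed, among the helicases and initiation factors. The heat early count was 3402 without the 0 min baseline, where the standing difference of the heat series enters, 1102 in a spline test of all times, 6 with array weights, 2 in the early arrays alone and 1 without 24 h. Without the baseline HSP104, HSP12, STF2, DDR2, NTH1, GAC1, SPG4, TIR1, SDH4, QCR10, MET28, ATG19, BIM1, GRX1, SOD2, MRP17 and MRPL31 turned negative and PRO1 and SMC3 positive, and 8 lists passed, of which 4 were among the 16 in the same direction, 3 passed in the opposite direction (oxidative phosphorylation, median -1.63, oxidative stress, -0.45, and mitochondrial ribosomal genes, -0.23) and 1 was not among them. Of the 16, 9 lost the call there, general stress (adjusted p = 0.872) and chaperones (0.305) included, and an early pulse fit called NAN1 alone, at -2.52 (adjusted p = 0.0030).

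From 2 to 24 h at 37 °C most of these groups had come back towards the start. Cytosolic ribosomal proteins were still lower (median -0.64, 115 of 127 negative, camera adjusted p = 1.7e-28, and 0.94 with an estimated correlation), and ribosome biogenesis genes slightly so (-0.32, 84 of 95 negative, adjusted p = 0.00015, and 0.95 with an estimated correlation), with NSA2 at -0.79 ± 0.52 and GAR1 at -0.73 ± 0.41. Sulfur amino acid genes, controlled by Met4, were higher (median 0.98, 21 of 23 positive, adjusted p = 2.7e-07, and 0.95 with an estimated correlation). DCV1 was the 1 gene past the threshold, higher by 2.62 ± 0.33 (adjusted p = 0.011), and higher at each of the 4 late times. Its level on the heat 0 min array was 6.3, under the 6.53 that bounds the dim genes, as were all 8 of its control arrays.

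In the sulfur group the sulfate permease SUL2 stood at 2.18 ± 0.70 and MET16, an enzyme of sulfate reduction, at 1.31 ± 0.41. Measured from its own start, the mean of this list was 0.79 in heat and -0.23 in the control at 2 h, and -0.32 and -0.91 at 8 h. RPS20 and RPS25A, small-subunit ribosomal proteins, had late changes of -1.78 ± 0.66 and -1.34 ± 0.47, with RPS20 under the dim bound on all 4 late heat arrays, and CDC33 had -1.40 ± 0.34. General stress genes were higher with a median of 0.47 (adjusted p = 0.038, and 0.95 with an estimated correlation), with HSP26 at 2.25 ± 1.73 and XBP1, a stress-induced repressor, at 0.72 ± 0.63. The other stress markers were HSP104 0.99 ± 0.98, SSA4 0.85 ± 0.78, HSP12 0.56 ± 0.78, CTT1 0.82 ± 1.48 and TPS1 0.21 ± 0.54. NSR1, so low early, stood at -0.67 ± 0.65, and OLE1 at -0.18 ± 0.65, TIP1 at -0.04 ± 0.35 and TIR1 at 0.23 ± 0.37.

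Iron regulon genes were lower late in heat (median -0.27, with the siderophore transporter SIT1 at -1.71 ± 0.62 and the ferroxidase FET3 at -0.68 ± 0.45), as were genes of the tricarboxylic acid cycle (-0.24). In the latter IDP1, the mitochondrial isocitrate dehydrogenase, stood at -1.25 ± 0.31 and CIT2, a peroxisomal citrate synthase, at -0.42 ± 0.33. Genes of meiosis and sporulation, a list of another cell state, were higher (0.34), with the septin SPR28 at 3.04 ± 0.68 and SPO74 at 1.93 ± 0.83, and so were mitotic genes (0.38, with NUD1 at 0.90 ± 0.65 and HST3, a histone deacetylase, at 1.33 ± 1.197). The mitotic list was low at 24 h in both cultures, at a mean of -1.11 from its start in heat and -2.16 in the control, and HST3 stood at -1.01 and -4.62 there. These 4 lists had adjusted p-values between 0.015 and 0.033, and between 0.94 and 0.95 with an estimated correlation. Both sporulation genes started near the background of the array, at log2 levels of 4.9 and 4.6 on the heat 0 min array. MMS21, a SUMO ligase, stood at 2.02 ± 0.35, AMA1 at 2.52 ± 0.52 and BRN1, a condensin subunit that lay under the dim bound on 6 control arrays, at 1.66 ± 0.38. YIL060W, under it on 3 of the 4 late heat arrays, was at -3.23 ± 0.83, the amino acid permease TAT1 at -1.46 ± 0.43 and the cell wall protein CCW12 at -1.31 ± 0.43, none past the threshold.

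In heat late limma called 1 gene, with 141 at an unadjusted p under 0.05. Camera passed 8 lists, 4 in each direction, and fry passed 0. Adjusted over the list alone, 2 genes passed, 1 higher in meiosis and sporulation and 1 lower in the tricarboxylic acid cycle. The heat late count was 0 with narrower windows, with 2 series alone, after renewed quantile normalization, and without 30 min, 2 h or 8 h, 3 without 24 h, 9 with array weights, 1102 in the spline test and 3837 without the baseline, where HSP104, HSP12, MET16, NSA2, NSR1 and TAT1 changed sign and, of the 8 lists, cytosolic ribosomal proteins alone passed, with ribosome biogenesis at a median of 0.73 (adjusted p = 0.415). Over the alternatives DCV1 ranged in adjusted p from 5.7e-09 without the baseline to 0.40 after renewed quantile normalization, with a change between 1.90 and 2.74.

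Within the first hour at 10 °C ribosome biogenesis genes were higher and stress, trehalose and chaperone genes were lower as groups, although no single gene passed the test. All 95 ribosome biogenesis genes had a positive early change, with a median of 1.51 (camera adjusted p = 5.9e-39, and 0.38 with an estimated correlation). General stress genes were lower, with a median of -1.95 and 40 of 41 negative (adjusted p = 4.6e-24, and 0.38 with an estimated correlation). Trehalose and glycogen genes were lower too, with a median of -1.74 and 16 of 17 negative (adjusted p = 2.9e-16, and 0.38 with an estimated correlation). Heat shock chaperones had a median of -0.44 with 28 of 32 negative (adjusted p = 2.8e-05, and 0.59 with an estimated correlation).

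Among ribosome biogenesis genes RRN11, a factor of RNA polymerase I, stood at 1.90 ± 0.58, SOF1, needed for small-subunit rRNA processing, at 1.56 ± 0.49, and NSR1 at 1.55 ± 0.68. Outside the list CGR1, an rRNA processing factor, had a value of 2.21 ± 0.66, the arginine methyltransferase HMT1 1.74 ± 0.50, the pseudouridine synthase PUS4 1.16 ± 0.33 and YGR079W 2.23 ± 0.65. The initiation factor genes TIF35 and NIP1 stood at 0.57 ± 0.36 and 0.63 ± 0.43, in a list with a median of 0.37 (adjusted p = 0.00062, and 0.51 with an estimated correlation). The list of cytosolic ribosomal proteins did not pass, and its mean change from 0 min was 0.02, 0.03 and 0.00 at 15, 30 and 60 min.

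Among chaperones the small heat shock protein HSP42 stood at -2.98 ± 0.52 (adjusted p = 0.27) and the mitochondrial disaggregase HSP78 at -2.24 ± 0.54. The trehalose phosphatase TPS2 had a change of -2.22 ± 0.58, its regulatory partner TSL1 -3.35 ± 0.98, TPS1 -1.19 ± 0.56 and the glycogen synthase GSY1 -3.18 ± 0.90. CTT1 stood at -3.34 ± 1.53, and at -4.03 from its start on the 60 min array. HSP26 was at -2.01 ± 1.79, HSP104 at -1.49 ± 1.02, SSA4 at -1.05 ± 0.81 and HSP12 at -0.61 ± 0.81. YER053C-A had the most negative value of the named genes (-4.11 ± 0.76, adjusted p = 0.27), with AFR1 at -1.51 ± 0.36 and YBR085C-A at -1.86 ± 0.45. Stationary phase genes (median -1.02, with PHM7 at -3.53 ± 1.17 and IGD1 at -2.29 ± 0.81) and autophagy genes (-0.77, with VPS30 at -1.31 ± 0.42 and ATG14 at -1.42 ± 0.70) were lower as lists. The same held for oxidative phosphorylation (-0.30, with SDH2 at -1.13 ± 0.52 and CYT1 at -0.90 ± 0.58), the tricarboxylic acid cycle (-0.26, with MDH2 at -1.02 ± 0.69) and oxidative stress defence (-0.29, with PRX1 at -1.30 ± 0.77). These 5 lists had adjusted p-values up to 0.047 at the preset correlation and from 0.38 to 0.92 with an estimated correlation. OLE1 stood at 0.83 ± 0.67, and the cold-shock cell wall genes TIP1 and TIR1 at 0.06 ± 0.36 and 0.16 ± 0.38.

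For single genes limma called 0 in cold early, with 252 at an unadjusted p under 0.05. Camera passed 10 lists (2 higher, 8 lower) and fry 0, and adjusted over the list alone 8 general stress genes, 9 trehalose and glycogen genes and 2 chaperones passed. The cold early count was 978 (526 higher, 452 lower) without the 0 min baseline, a fit in which 90 of 95 ribosome biogenesis genes rose and 31 of 41 general stress genes fell, and HSP42 stood at -3.26 (adjusted p = 1.9e-05). The early pulse, whose reference includes 2 to 8 h, gave 755, and the spline test of any change over all times gave 2989. The cold early count was 247 with array weights, 4 in the early arrays alone and 3 without 2 h, and TIP1 changed sign without the baseline.

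From 2 to 24 h at 10 °C cold-inducible genes, seripauperins and lipid synthesis genes were higher, and cytosolic ribosomal proteins were lower. All 12 cold-inducible genes were positive, with a median of 0.57 (camera adjusted p = 0.0033, fry 0.021, and 0.13 with an estimated correlation). The seripauperin family, cell wall proteins of anaerobic and cold-grown cells, had a median of 0.79 with 11 of 13 positive (adjusted p = 0.0033, and 0.90 with an estimated correlation). Cytosolic ribosomal proteins had a median of -0.40 with 120 of 127 negative (adjusted p = 4.3e-08, and 0.98 with an estimated correlation). Their mean change from 0 min went from -0.17 at 2 h to -1.01 at 24 h, where all 127 were below their start, against -0.14 in the control.

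TIR4, a cell wall mannoprotein, stood at 2.72 ± 0.60 and LOT6, a quinone reductase, at 1.34 ± 0.52. TIP1 and TIR1 had smaller values, 0.54 ± 0.35 and 0.59 ± 0.37. PAU24 and PAU9 were at 1.67 ± 0.40 and 1.09 ± 0.34. In lipid synthesis (median 0.59, adjusted p = 0.0065, and 0.98 with an estimated correlation) INO1, the inositol synthase, stood at 2.95 ± 0.70 and the choline kinase CKI1 at 1.16 ± 0.38, while OLE1 was at 0.59 ± 0.65. The control moved in both lists by 24 h: lipid synthesis genes stood at a mean of -1.36 from their start there and -0.15 in cold, and seripauperins at 1.06 there and 1.42 in cold. HMX1, the heme oxygenase, had a change of 4.09 ± 0.77, YGR035C 4.60 ± 0.98, YMR085W 3.13 ± 0.66, the mediator kinase SSN3 1.70 ± 0.34 and YLR415C 1.39 ± 0.30. Proteasome genes were slightly higher (median 0.39, 31 of 33 positive, adjusted p = 0.0012, and 0.98 with an estimated correlation), with SCL1 at 0.78 ± 0.29 and PUP3 at 0.72 ± 0.36.

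**Figure D3:**
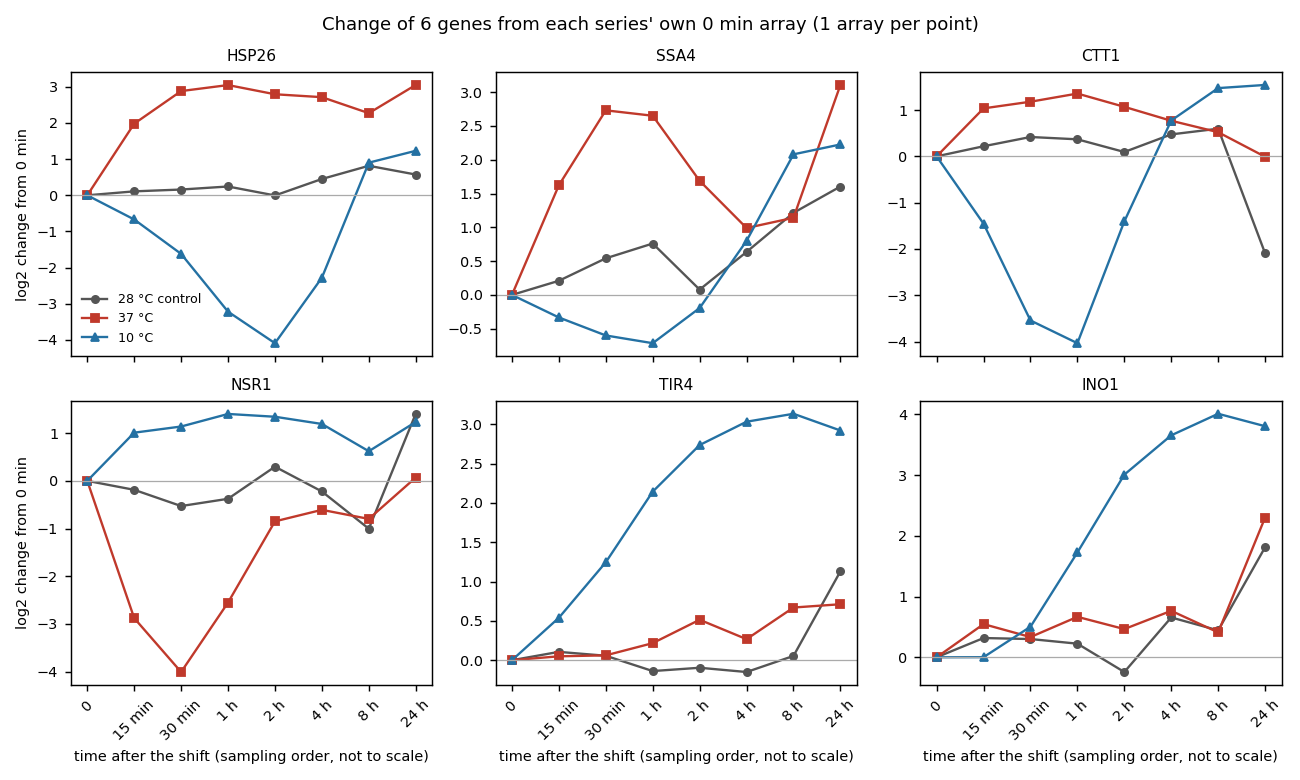
Each panel shows the log2 change of 1 gene from the series' own 0 min array (vertical axis) at the 8 sampling times in order (horizontal axis), with 1 line per temperature and 1 array per point. TIR4 and INO1 climb in the cold series to 3.13 and 4.01 at 8 h, and CTT1 goes from -4.03 at 60 min to 1.54 at 24 h there.

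On the lower side late in cold, RPS9A, a small-subunit ribosomal protein, stood at -2.97 ± 0.59 and RPL22B at -2.12 ± 0.57. VPS30, an autophagy and sorting protein, was at -2.54 ± 0.41, the repressor NRG2 at -1.97 ± 0.40, CHA4, an activator of serine breakdown, at -1.83 ± 0.38 and the methyltransferase MTQ2 at -1.48 ± 0.31. The arginine and histidine enzymes ARG3 and HIS6 stood at -3.07 ± 0.94 and -1.44 ± 0.38 in an amino acid list with a median of -0.31 (adjusted p = 0.0036, and 0.98 with an estimated correlation). POL12, a DNA polymerase subunit, and the cyclin CLB5 were at -1.96 ± 0.66 and -1.15 ± 0.46, and S phase genes had a median of -0.57 (adjusted p = 0.0077, and 0.98 with an estimated correlation). The control culture moved in this list too, to a mean of -3.27 at 24 h, against -2.09 in cold. Oxidative phosphorylation genes had a median of -0.28 (adjusted p = 0.043, and 0.98 with an estimated correlation), with ATP19 at -1.41 ± 0.44 and QCR6 at -1.50 ± 0.72. Measured from its own start, the late mean of this list was 0.05 in cold and 0.34 in the control, so the control's rise enters this value. Mating genes, a mixed list of mating type a, alpha and pheromone genes, were higher (0.65, adjusted p = 0.043, 0.073 without the 0 min baseline, and 0.98 with an estimated correlation), with the a-factor gene MFA2 at 2.07 ± 0.83 and ASG7 at 1.32 ± 0.48. The mean of the mating list at 24 h was 1.09 from its start in cold and -0.66 in the control. The stress markers did not pass, with HSP104 at -0.16 ± 0.98, SSA4 at 0.34 ± 0.78, HSP12 at 0.01 ± 0.78, CTT1 at 0.83 ± 1.48, TPS1 at 0.67 ± 0.54 and HSP26 at -1.52 ± 1.73, and NSR1 was at 0.98 ± 0.65. These means average times that differ, since relative to the control CTT1 ran, between 2 h and 24 h, from -1.50 to 3.63 and HSP12 from -1.03 to 0.87.

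For single genes limma called 0 in cold late, with 548 at an unadjusted p under 0.05, and the named values had adjusted p-values of at least 0.15. Camera passed 9 lists (5 higher, 4 lower) and fry 1, and adjusted over the list alone 1 cold-inducible gene, 2 seripauperins, 1 lipid gene and 1 ribosomal protein gene passed. The cold late count was 1640 (882 higher, 758 lower) without the baseline, a fit in which TIR4 stood at 2.52 (adjusted p = 3.8e-05), INO1 at 2.54 (0.00011) and VPS30 at -2.41 (5.4e-06). It was 794 with array weights, 2989 in the spline test, 1 with narrower windows, 1 without 2 h and 0 without 24 h, while CTT1 was -0.11 without 24 h.

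Set directly against each other in the first hour, heat and cold differed in 272 genes, 117 higher and 155 lower in heat. Of 95 ribosome biogenesis genes 52 were lower in heat (92 adjusted over the list alone), with a list median of -3.04, and none was called higher. Of 41 general stress genes 13 were higher (29 adjusted over the list alone), with a median of 2.99, and of 17 trehalose and glycogen genes 8 (12 adjusted over the list alone), with a median of 2.50. Of 32 chaperones 4 were higher (7 adjusted over the list alone, and 1 lower). Among the 117 genes higher in heat, 115 lay above their own 0 min level in heat and below it in cold at all 3 early times. Among the 155 lower genes, 154 did the reverse. Of all 5449 genes, 1276 showed the first pattern and 1094 the second, and the called genes were selected on the difference of these changes from 0 min, which favours both patterns.

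CYC7, a cytochrome c of stressed and oxygen-limited cells, differed by 7.40 ± 1.36 (adjusted p = 0.016), YER053C-A by 6.32 ± 0.76 (0.0058) and YNL194C, a membrane protein, by 6.20 ± 1.56 (0.040). TOD6, a repressor of ribosome biogenesis genes, differed by -5.47 ± 1.19 (adjusted p = 0.024), the helicase DHR2 by -5.41 ± 1.09 (0.020), SSF1, a large-subunit assembly factor, by -5.22 ± 1.12 (0.023) and NSR1 by -4.33 ± 0.68 (0.010). CYC7 started at a log2 level of 5.3 on the heat array and 10.5 on the cold array. In the early window TOD6 lay under the dim bound on 2 of 3 heat arrays and DHR2 and SSF1 on 1, while CYC7 and YNL194C did on 2 of 3 cold arrays, so the sizes of these differences are uncertain. Not past the threshold were SSA4 (2.88 ± 0.81, adjusted p = 0.057), TPS1 (1.90 ± 0.56, 0.068), HSP104 (3.24 ± 1.02, 0.078), CTT1 (4.20 ± 1.53, 0.13), HSP26 (4.47 ± 1.79, 0.17), HSP12 (1.78 ± 0.81, 0.23), OLE1 (-1.39 ± 0.67, 0.26), TIR1 (-0.15 ± 0.38, 0.89) and TIP1 (0.02 ± 0.36, 0.98).

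Camera passed 15 lists in this comparison, 10 higher and 5 lower, with a smallest adjusted p of 0.34 with an estimated correlation. Fry passed 6 of them at 0.031, namely ribosome biogenesis, general stress, trehalose and glycogen, stationary phase (median 2.64), helicases and initiation factors (-0.76) and autophagy (1.15). Stationary phase genes had 2 of 20 higher (6 adjusted over the list alone), autophagy 1 of 19 (4) and helicases 1 of 26 lower (3). Cytosolic ribosomal proteins were lower in heat with a median of -0.90, and 1 of 127 was called (0 adjusted over the list alone). Of 24 tricarboxylic acid cycle genes (median 0.47) 0 were called over all genes, and 4 higher and 1 lower adjusted over the list alone. Also higher were oxidative phosphorylation (0.58), oxidative stress (0.67), proteasome (0.26) and mitochondrial ribosomal genes (0.25), and amino acid (-0.66) and S phase genes (-0.84) were lower. The heat against cold early count was 0 without 30 min and 0 with these 2 series alone, 46 without 60 min and 65 without 4 h. It was 885 without 24 h, 1081 in the early arrays alone, 1342 with array weights, 3741 without the baseline, 179 without the time block and 65 with narrower windows.

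Late heat and late cold differed in 6 genes. YDL085C-A was higher in heat by 3.48 ± 0.50 (adjusted p = 0.023), VPS30 by 2.53 ± 0.41 (0.049), DCV1 by 2.33 ± 0.33 (0.023), and MMS21 and TDA2 by 2.06 each (0.049). IDP1 was lower by -1.80 ± 0.31 (adjusted p = 0.049). Cold-inducible genes were lower in heat as a list, with a median of -0.85 and 11 of 12 negative (camera adjusted p = 0.0012, fry 0.0071, and 0.076 with an estimated correlation). MMS21 and DCV1 lay under the dim bound on all 8 cold arrays, so the sizes of their differences are uncertain. MMS21 and TDA2 stand outside the rule for named genes and were added after their values were seen.

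At 8 h VPS30 stood at -2.41 from its own start in cold and 0.46 in heat. IDP1 stood at -1.63 in heat and 0.29 in cold. YDL085C-A reversed to -1.22 without the baseline, and its level on the heat 0 min array, 6.2, lay under the dim bound. PAU24 stood at -2.24 ± 0.40 (adjusted p = 0.050) and PPM1 at -2.06 ± 0.40 (0.072). The stress markers did not pass in this window either, with HSP26 at 3.77 ± 1.73 (adjusted p = 0.36), HSP104 at 1.15 ± 0.98, SSA4 at 0.50 ± 0.78, HSP12 at 0.55 ± 0.78, TPS1 at -0.46 ± 0.54 and CTT1 at -0.01 ± 1.48. NSR1 was at -1.65 ± 0.65, OLE1 at -0.77 ± 0.65, TIP1 at -0.58 ± 0.35 and TIR1 at -0.36 ± 0.37. Camera passed 12 lists. S phase (median 1.00), sulfur amino acid (1.09) and chaperone genes (0.26) were higher in heat. Proteasome (-0.41), tricarboxylic acid cycle (-0.39), seripauperin (-0.61), lipid synthesis (-0.67), ribosome biogenesis (-0.36), mating (-0.65), glucose-repressed (-0.63) and helicase genes (-0.42) were lower. All 11 had an adjusted p of 0.94 with an estimated correlation, and fry passed none of them. Adjusted over the list alone, 2 chaperones were higher, and 2 tricarboxylic acid cycle genes (1 over all genes), 2 seripauperins, 1 cold-inducible gene, 1 mating gene and 1 helicase were lower.

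At an unadjusted p under 0.05 there were 734 genes. The heat against cold late count was 0 with narrower windows, with 2 series alone, after renewed quantile normalization, with a variance trend and without 30 min, 4 h or 8 h, 2 without 15 min or dim genes, 16 without 2 h, 10 without the time block or after median centring, 354 without 24 h, 826 with array weights and 3861 without the baseline.

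Between the early and late windows at 37 °C, ribosome biogenesis genes were higher late and stress lists lower. Of 95 ribosome biogenesis genes 94 were higher late than early, with a median of 1.24 (camera adjusted p = 2.4e-30, and 0.58 with an estimated correlation), and 40 passed when adjusted over the list alone, against 0 over all genes. S phase genes were higher by a median of 0.98 (adjusted p = 3.9e-08, and 0.58 with an estimated correlation). These values are relative to the control, and on the heat arrays alone the S phase median was 0.36 against -0.75 on the control arrays, or 0.84 against 0.12 without 24 h. General stress genes were lower by a median of -0.62 (adjusted p = 0.00010, and 0.58 with an estimated correlation), with 37 of 41 negative. Past the threshold were 4 genes, all higher late: SPR28 by 3.04 ± 0.47, NAN1 by 2.57 ± 0.38, MMS21 by 1.84 ± 0.24 and DCV1 by 1.53 ± 0.23 (adjusted p = 0.016 to 0.021). DCV1 stands outside the rule for named genes here and was added after its value was seen.

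NAN1 lay under the dim bound in the heat series, at a mean log2 level of 6.43, and SPR28 and MMS21 in the control, at 4.61 and 5.15. NSR1 stood at 2.12 ± 0.45 (adjusted p = 0.21). RSM10, a mitochondrial ribosomal protein, was at -0.95 ± 0.21, RCF1, a respiratory supercomplex factor, at -1.34 ± 0.31 and ARG82 at -1.77 ± 0.41, with adjusted p-values of 0.25 to 0.27. The markers SSA4 (-0.98 ± 0.53), HSP104 (-0.76 ± 0.67), HSP12 (-0.62 ± 0.53), TPS1 (-0.50 ± 0.37), HSP26 (-0.22 ± 1.18), TIP1 (-0.12 ± 0.24), CTT1 (-0.04 ± 1.01), TIR1 (0.21 ± 0.25) and OLE1 (0.38 ± 0.44) did not pass. Lower late as lists were stationary phase (median -1.10), glucose-repressed (-0.71), tricarboxylic acid cycle (-0.51), trehalose and glycogen (-0.50), mitochondrial ribosomal (-0.38), oxidative phosphorylation (-0.35), oxidative stress (-0.34), chaperone (-0.30) and proteasome genes (-0.27). Higher were mitotic (0.48), sulfur amino acid (0.33), amino acid (0.28), helicase (0.26), cytosolic ribosomal (0.20) and ergosterol genes (0.19). Their adjusted p-values with an estimated correlation were 0.58 to 0.67. On the heat arrays alone the late against early medians of mitotic (-0.04), sulfur amino acid (-0.16) and ergosterol genes (-0.12) were negative, and those on the control arrays were lower still, at -0.65, -0.56 and -0.46. Oxidative phosphorylation (-0.07), chaperone (-0.06) and glucose-repressed genes (-0.15) lay close to 0 in heat alone and at 0.27, 0.22 and 0.50 in the control.

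Camera passed 18 lists (8 higher, 10 lower), fry passed 0, adjusted over the list alone 1 trehalose and glycogen gene was lower, and 639 genes had an unadjusted p under 0.05. The heat late against early count was 0 with narrower windows, after renewed quantile normalization and without 15 min, 30 min or 4 h, 1 with 2 series alone or without 8 h, 2 without dim genes, 8 without 24 h and 166 with array weights.

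At 10 °C the early and late windows differed in 815 genes, 425 higher and 390 lower late, and several of the lists that had differed early moved back. Chaperones (camera adjusted p = 0.075), helicases and initiation factors (0.37) and oxidative phosphorylation (0.75) did not pass. Of 41 general stress genes 23 rose from early to late (28 adjusted over the list alone), with a median of 2.16 and all 41 positive. Of 17 trehalose and glycogen genes 12 rose (14 adjusted over the list alone), with a median of 1.93. Of 95 ribosome biogenesis genes 32 fell (56 adjusted over the list alone), with a median of -1.39. Among the 425 higher genes, 332 lay below their own 0 min level early and above it late. Among the 390 lower genes, 226 did the reverse, and 117 were below it in both windows. Of all 5449 genes 1254, 1082 and 1592 did so, and selection on the difference between windows favours the first 2 patterns.

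RTN2, a reticulon, rose by 4.73 ± 1.15 (adjusted p = 0.017), PHM7 by 4.57 ± 0.77 (0.0049), YNL194C by 4.31 ± 1.03 (0.016), CTT1 by 4.17 ± 1.01 (0.017) and TPS1 by 1.86 ± 0.37 (0.0089). LTV1, a factor of small-subunit export, changed by -3.37 ± 0.73 (adjusted p = 0.011), TEA1, a transcriptional activator, by -3.33 ± 0.73 (0.011) and the transporter AQR1 by -3.28 ± 0.48 (0.0027). These values are relative to the control, which moved too. At 24 h it stood from its start at 2.13 for LTV1, 2.90 for TEA1 and 2.24 for AQR1, and at -1.47 for RTN2 and -2.09 for CTT1. This enlarges their values, whereas for YNL194C the control stood at 3.52, which lessens its value. SSA4 (1.40 ± 0.53, adjusted p = 0.093), HSP104 (1.34 ± 0.67, 0.19), TIP1 (0.48 ± 0.24, 0.19), TIR1 (0.43 ± 0.25, 0.27), NSR1 (-0.57 ± 0.45, 0.41), HSP12 (0.62 ± 0.53, 0.46), OLE1 (-0.24 ± 0.44, 0.75) and HSP26 (0.49 ± 1.18, 0.81) did not pass. HSP26 had its minimum in cold at 2 h, at -4.09 from its start, and stood at 0.90 by 8 h.

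Autophagy genes were higher late (median 0.99, with 6 of 19 higher and 1 lower, or 11 and 1 adjusted over the list alone). Stationary phase genes (0.98, 6 of 20, or 7 and 1 lower adjusted over the list alone), proteasome genes (0.50, 2 of 33 by either adjustment), tricarboxylic acid cycle genes (0.70, 1 of 24, or 0 adjusted over the list alone) and lipid synthesis genes (0.39, 4 of 31 by either adjustment) were higher too, the last with a median of 0.05 on the cold arrays alone and -0.46 on the control arrays. So were oxidative stress (0.53, 2 of 31 higher and 1 lower by either adjustment) and glucose-repressed genes (0.71, 3 of 29 higher and 1 lower by either adjustment). Cytosolic ribosomal proteins (-0.43, 8 of 127, or 4 adjusted over the list alone), amino acid genes (-0.65, 8 of 60 by either adjustment) and S phase genes (-0.73, 5 of 30, or 8 adjusted over the list alone) were lower. Camera passed these 13 lists, with adjusted p-values of 0.62 to 0.89 with an estimated correlation. Fry passed 6, general stress, trehalose and glycogen, proteasome, autophagy, the tricarboxylic acid cycle and cold-inducible genes (median 0.45, 2 of 12 higher, or 3 adjusted over the list alone), at 0.017 to 0.027. At an unadjusted p under 0.05 there were 1690 genes. The cold late against early count was 26 without 30 min, 55 without 15 min, 308 without 60 min, 345 without 4 h, 487 without 8 h, 1348 without 24 h, 541 with narrower windows and 3542 with array weights.

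In the control culture, held at 28 °C, the late window had lower S phase and sulfur amino acid genes and higher respiratory genes than the first hour, and much of this rested on the 24 h array. S phase genes had a median of -0.79 with all 30 negative (camera adjusted p = 0.00032, and 0.63 with an estimated correlation), and sulfur amino acid genes -0.58 (adjusted p = 9.3e-09, and 0.63 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.29 with 39 of 40 positive (adjusted p = 4.1e-07, and 0.63 with an estimated correlation), and glucose-repressed genes 0.56 (adjusted p = 0.00032, and 0.63 with an estimated correlation). Measured from the start, the mean of the glucose-repressed list was 0.25 at 8 h and 2.48 at 24 h, that of S phase genes -0.37 and -3.27, and that of oxidative phosphorylation 0.17 and 1.03. The sulfur amino acid list already stood at -0.91 at 8 h, and at -1.27 at 24 h. Set against 15 to 60 min, the median of the late control arrays was -0.75 for S phase genes and 0.12 without 24 h, 0.27 and 0.07 for oxidative phosphorylation, 0.50 and -0.02 for glucose-repressed genes, and -0.56 and -0.36 for sulfur amino acid genes.

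FLO1 and FLO9, flocculins of the cell surface, stood at 1.69 ± 0.36 and 0.97 ± 0.24, the protease YPS3 at 0.77 ± 0.17, the peptide transporter PTR2 at -1.90 ± 0.53, the sulfur regulator MET32 at -0.74 ± 0.20 and GSY1 at -0.54 ± 0.15, all with an adjusted p of 0.65. The markers were SSA4 0.51 ± 0.34, NSR1 0.39 ± 0.46, HSP26 0.33 ± 0.18, HSP104 0.21 ± 0.15, OLE1 0.11 ± 0.11, TPS1 -0.13 ± 0.14, HSP12 -0.15 ± 0.17, TIP1 -0.15 ± 0.22, TIR1 -0.30 ± 0.13 and CTT1 -0.48 ± 0.56. Lower late as lists were also mitotic (median -0.68), ergosterol (-0.47), lipid synthesis (-0.46), oxidative stress (-0.23), mitochondrial ribosomal (-0.12), helicase (-0.12), proteasome (-0.09) and cytosolic ribosomal genes (-0.06). Higher were seripauperin (0.47), hexose transporter (0.34), stationary phase (0.32), meiosis (0.27), chaperone (0.24) and ribosome biogenesis genes (0.18). Their adjusted p-values with an estimated correlation were 0.63 to 0.79. In the same measure against 15 to 60 min, leaving out 24 h took ergosterol genes from -0.46 to -0.04, lipid synthesis from -0.46 to -0.07, mitotic genes from -0.65 to -0.16, oxidative stress from -0.22 to -0.06, chaperones from 0.22 to 0.0030, hexose transporters from 0.30 to 0.010, seripauperins from 0.52 to 0.16, stationary phase from 0.28 to 0.17 and ribosome biogenesis from 0.26 to -0.0047.

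Limma called 0 genes in the control series, with 155 at an unadjusted p under 0.05, and 0 again without 24 h. Camera passed 18 lists (8 higher, 10 lower) and fry 0. With the settings of the comparisons above 5 lists passed camera in none of them, namely cell wall integrity, glycolysis and fermentation, histones, the phosphate regulon and the unfolded protein response, with a smallest adjusted p of 0.055. Without the 0 min baseline histones passed as lower in heat early (adjusted p = 0.013) and heat late (0.044).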

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

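The tests of a constant offset, of a heat response at 0 min, of growth stage, of the cold 0 min array, of drift in the control culture and of exchanges within a window were chosen after the results were seen, and the drift tests and the exchanges replaced earlier versions whose values had been seen.

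The heat series stood apart from the control at 0 min, with 2397 genes at least 2-fold apart, and HSP26 on its 0 min array lay at 11.6 against 13.6 to 14.7 on its later arrays. A heat response under way as the whole cause is argued against by the ribosome biogenesis genes, which were lower at 15 to 60 min. At 0 min they were higher in heat (median 1.07, 78 of 95 higher, and 0.64 above genes of like length). General stress (-0.39), stationary phase (-1.48) and oxidative stress genes (-1.02), higher early in heat, ran against it too. Chaperones (0.30) and trehalose genes (0.33) lay close to the median of all genes, 0.29. Glucose-repressed genes (0.71) and ribosomal proteins (-1.47) ran its way, although the shortest genes as a whole had a median of -1.01. A part of such a response beneath an offset therefore stays open. An offset that stays in the series may account for the difference, since the lowest correlation across genes of the 0 min difference with that at a later time was 0.807. Loss of short transcripts in the added amplification step is consistent with the rank correlation of 0.394 between coding length and the difference. A different state of the heat culture before the shift was not tested and stays open.

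The 24 h arrays stood apart from the others of their series, most clearly in the control (mean r with its other arrays 0.745, against 0.942 to 0.956) and in heat (0.849, against 0.909 to 0.948). A growth stage reached by 24 h is a candidate explanation, since the mean of the glucose-repressed list lay at least 1.51 above its start in both series. A hybridisation artefact cannot be told apart, because the spread of other-species probe sets at 24 h in the control was 1.38 times its median at other times, between the bounds set for and against it. In heat this ratio was 1.16, but its spread was already larger at other times (0.285, against 0.154 in the control) and the variance added at 24 h, 0.0276 against 0.0212, was no smaller, so the ratio decides nothing there either. No label gives the density of the cultures.

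The early cold changes of stress and ribosome biogenesis genes were lost or turned late. Without the 0 min baseline the ribosome biogenesis change shrank but was not lost, with a median of 1.85 early and 0.42 late (camera adjusted p = 0.0044 late). The general stress change was lost there but not turned, with a median of -2.49 early and 0.05 late (camera adjusted p = 0.98 late). A cold 0 min array out of place is argued against, as the source of the difference between windows, by the stress list. Its late against early median, which uses no 0 min array, was 2.16. The 24 h arrays alone are argued against by this median without them, 1.72. Whether a list went past its start rests on the 0 min array, so these medians cannot decide it. Drift of the control is argued against by the cold arrays taken alone, where late minus early means were 2.02 for stress genes and -1.16 for ribosome biogenesis genes. An acclimation of the culture to 10 °C may account for the turn, as a hypothesis, and the growth of the culture over 24 h, untested in cold, stays open beside it.

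Single arrays far from the rest of their series were found in 37 of 126 series-by-measure groups. About 6.3 would be flagged by chance if the 8 arrays of a series were exchangeable draws. They are ordered times, and the groups are read from the same 24 arrays, with most flags on the 24 h arrays. The excess therefore cannot be counted as separate events. On the control 24 h array the mean log2 levels of heat shock chaperones (13.2, others 12.2 to 12.4), oxidative phosphorylation (13.4, others 12.4 to 12.5), the tricarboxylic acid cycle (12.5, others 11.9 to 12.0), glucose-repressed genes (11.3, others 8.80 to 9.05) and hexose transporters (10.8, others 9.87 to 10.1) lay above the others. Below them lay cold-inducible genes (10.6, others 10.7 to 10.8), glycolysis (13.7, others 14.0 to 14.1), ergosterol synthesis (10.8, others 12.2 to 12.5), lipid synthesis (10.6, others 11.7 to 12.0), amino acid synthesis (12.2, others 12.6 to 12.9), the proteasome (12.3, others 12.5 to 12.6) and oxidative stress defence (11.7, others 12.1 to 12.2). So did cell wall genes (12.0, others 12.8 to 13.0), the unfolded protein response (10.5, others 11.6 to 11.9), histones (12.3, others 13.5 to 13.7), S phase genes (7.93, others 10.8 to 11.3), mitotic genes (8.54, others 10.3 to 10.7) and mating genes (9.75, others 10.2 to 10.4). Of the fixed genes, HSP12 (14.1, others 14.6 to 14.8), CTT1 (11.3, others 13.4 to 14.0), TPS1 (13.4, others 13.7 to 13.9) and TIP1 (13.6, others 14.4 to 14.5) were low there. At 8 h the control stood apart in autophagy (9.81, others 9.35 to 9.53), helicases and initiation factors (11.7, others 12.0 to 12.1) and mitochondrial ribosomal proteins (10.97, others 11.31 to 11.42).

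In heat at 24 h ergosterol synthesis (11.2, others 11.9 to 12.3), mitotic genes (9.77, others 10.5 to 11.1), mating genes (9.01, others 9.81 to 10.3) and TIP1 (13.6, others 14.3 to 14.5) were low, and at 8 h TIR1 was low (8.72, others 9.22 to 9.55). In cold at 24 h the unfolded protein response (11.2, others 11.5 to 11.6), histones (13.1, others 13.3 to 13.5) and mitochondrial ribosomal proteins (11.3, others 11.4 to 11.5) were low and mating genes high (11.4, others 10.3 to 10.6).

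Several tests of a difference between groups passed. Heat and cold differed in 272 genes early and 6 late, and the windows in 4 genes in heat and 815 in cold. Early heat against cold list medians that passed fry were -3.04 for ribosome biogenesis, 2.99 for general stress, 2.50 for trehalose and glycogen, 2.64 for stationary phase, -0.76 for helicases and initiation factors and 1.15 for autophagy, and late that of cold-inducible genes was -0.85. Late against early in cold they were 2.16 for general stress, 1.93 for trehalose and glycogen, 0.50 for the proteasome, 0.99 for autophagy, 0.70 for the tricarboxylic acid cycle and 0.45 for cold-inducible genes. Among genes, heat against cold early gave CYC7 7.40, YER053C-A 6.32, YNL194C 6.20, TOD6 -5.47, DHR2 -5.41, SSF1 -5.22 and NSR1 -4.33, and heat against cold late gave YDL085C-A 3.48, VPS30 2.53, DCV1 2.33 and IDP1 -1.80. Late against early gave SPR28 3.04, NAN1 2.57 and MMS21 1.84 in heat, and RTN2 4.73, PHM7 4.57, YNL194C 4.31, CTT1 4.17, TPS1 1.86, LTV1 -3.37, TEA1 -3.33 and AQR1 -3.28 in cold.

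Of the probe sets without a name here, 261 were brighter than every other-species probe set. Of these 37 passed in cold late against early, 5 in heat against cold early, 2 in heat against cold late, 1 in cold late and 0 with limma in the remaining comparisons of the heat and cold series.

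Other assignments of the same arrays were fitted to see how often results as large arise. For the heat late against early count 1 of 35 splits, the real one, gave 4 genes and the highest other gave 1, so chance can be excluded only as far as the ordered times of 1 culture can be exchanged, and the count was 0 with narrower windows, after renewed quantile normalization and without 15 min, 30 min or 4 h. By the same rule chance cannot be excluded for the cold late against early count of 815, where 2 of 35 splits gave as many. The other one, 898, set 15 min to 2 h against 4 to 24 h. That is the ordered division moved by 1 time, so it holds the same trend and is no unrelated regrouping. The highest of the remaining splits gave 33. Chance cannot be excluded for the lists either. They were matched by 4 of 35 splits in heat late against early (real 18, highest other 21), 30 of 35 in cold late against early (13 and 21) and 9 of 35 in the control (18 and 21). For the control count all 35 splits gave 0, which decides nothing.

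For the comparisons between series, the 2 series were exchanged at any of the times of the tested window, with 0 min in place, which makes 8 splits early and 16 late, too few for a share under 0.05. In heat early 8 splits gave at least the real count of 0, a certain outcome (highest other 3312), and 1 gave the 16 lists (highest other 8). In cold early 8 gave at least 0 genes (highest other 19) and 5 the 10 lists (highest other 17). In heat late 3 gave the count of 1 (highest other 3500) and 12 the 8 lists (highest other 12), and in cold late 16 gave at least 0 genes (highest other 15) and 12 the 9 lists (highest other 17). Heat against cold early was matched by 2 splits in its count of 272 (highest other 3375) and by 1, the real one, in its 15 lists (highest other 11). Heat against cold late was matched by 3 in its count of 6 (highest other 3471) and by 1, the real one, in its 12 lists (highest other 10). The splits with 3312 to 3500 genes exchange heat over the whole window while 0 min stays in place, so they point to the standing difference of the heat series.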

How the results depend on the processing

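The fits of the early arrays alone and of an early pulse were chosen after the data were seen. Across all alternatives 86 counts stayed within 1.5 times, 35 were larger and 35 smaller; 147 list counts stayed so and 21 were smaller. Of the values of named genes 3542 kept direction and side of the threshold, 214 passed it newly, 104 lost it and 62 changed sign, of which 1, YDL085C-A in heat against cold late, had passed. Most of the 3542 had passed neither in the main fit nor in the alternative. Of the 23 named results past the threshold, 22 lost it without 30 min and 15 with 2 series alone. Without 15 min 11 lost it, and 11 without 4 h, against 0 with array weights, median centring or without 24 h. For the changes below the cause was not tested, unless the setting itself gives it. Dim signal, 1 or more arrays of a series under the bound of 6.53, limits 29 of 135 named genes (25 in heat, 14 in cold, 9 in the control). They are DCV1, SPR28, MMS21, NAN1, CYC7, YDL085C-A, TOD6, DHR2, SSF1 and YNL194C among those past the threshold in some comparison, and ADY2, AMA1, ARG82, ATG19, BIM1, BRN1, CDC33, CGR1, GAC1, HST3, MET28, RPS20, SDH4, SPO74, YGL258W-A, YGR035C, YIL060W, YLR415C and YOR032W-A. The single 0 min array per series limits every comparison that subtracts it.

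Without the 0 min baseline the counts were heat early count 3402, heat late count 3837, cold early count 978, cold late count 1640, heat against cold early count 3741 and heat against cold late count 3861, and the gene list tests, heat early gave 8 (4 of the 16 in the same direction, 3 turned) and the gene list tests, heat late 5 (1 of the 8). In heat early, values turned to -4.31 for ATG19, -3.13 for BIM1, -3.18 for DDR2, -0.22 for GAC1, -2.01 for GRX1, -0.86 for HSP104, -0.33 for HSP12, -5.50 for MET28, -1.36 for MRP17, -0.75 for MRPL31, -3.69 for NTH1, 0.78 for PRO1, -3.71 for QCR10, -5.62 for SDH4, 0.16 for SMC3, -0.54 for SOD2, -0.64 for SPG4, -0.25 for STF2 and -0.10 for TIR1. In heat late they turned to -1.62 for HSP104, -0.95 for HSP12, -0.46 for MET16, 0.16 for NSA2, 0.43 for NSR1 and 0.65 for TAT1. In heat against cold late they turned to 0.61 for CTT1, -1.50 for HSP104, -0.87 for HSP12 and -1.22 for YDL085C-A, in cold late to -0.077 for HSP12 and -0.25 for SSA4, and in cold early to -0.19 for TIP1.

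With array weights the heat early count was 6, heat late count 9, cold early count 247, cold late count 794, heat against cold early count 1342, heat against cold late count 826, heat late against early count 166 and cold late against early count 3542. CTT1 turned to 0.27 in heat against cold late, HSP104 to 0.015 and HSP12 to -0.066 in cold late, and HSP26 to -0.72 and OLE1 to 0.28 in cold late against early. In the early arrays alone the heat early count was 2, cold early count 4 and heat against cold early count 1081, and for an early pulse the heat early count was 1 and cold early count 755. The spline gave 1102 for the heat early count and heat late count and 2989 for the cold early count and cold late count.

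Narrower windows gave a heat late count of 0, cold late count of 1, heat against cold early count of 65, heat against cold late count of 0, heat late against early count of 0, cold late against early count of 541 and 4 in the gene list tests, heat late, with TIR1 at 0.00125 in heat against cold early. With the 2 compared series alone the heat late count, heat against cold early count and heat against cold late count were 0 and the heat late against early count 1. Without a time block the heat against cold early count was 179 and heat against cold late count 10. Without dim probe sets the heat against cold late count and heat late against early count were 2 each. Renewed quantile normalization gave 0 for the heat late count, heat against cold late count and heat late against early count, CTT1 at 0.066 in heat against cold late and HSP12 at -0.024 in cold late. Median centring gave a heat against cold late count of 10, CTT1 at 0.0080 in heat against cold late, HSP12 at -0.0093 in cold late and TIR1 at -0.017 in heat early. A variance trend gave a heat against cold late count of 0.

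With an estimated correlation 0 lists passed in the gene list tests, heat early, and likewise 0 in each of the other 8 comparisons. Fry passed 0 in the gene list tests, heat early, heat late, cold early, heat late against early and control late against early, 1 in cold late and heat against cold late, and 6 in heat against cold early and cold late against early.

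Leaving out 1 time at a time gave a heat early count of 0 to 1, heat late count of 0 to 3, cold early count of 0 to 3, cold late count of 0 to 1, heat against cold early count of 0 (30 min) to 885 (24 h), heat against cold late count of 0 to 354 (24 h), heat late against early count of 0 to 8 and cold late against early count of 26 (30 min) to 1348 (24 h). CTT1 ranged from -0.11 to 1.60 in cold late, -0.76 to 0.14 in the control, -0.84 to 0.51 in heat against cold late and -0.46 to 0.26 in heat late against early. HSP12 ranged from -0.27 to 0.36 in cold late, HSP26 from -0.24 to 1.34 in cold late against early and -0.52 to 0.047 in heat late against early, and OLE1 from -0.44 to 0.19 in cold late against early. NSR1 ranged from -0.037 to 0.77 and TIP1 from -0.23 to 0.075 in the control, TIP1 from -0.014 to 0.042 and TIR1 from -0.27 to 0.00125 in heat against cold early, and TIR1 from -0.13 to 0.12 in heat early.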

Other observations

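The lists and times described first were chosen after their values were seen, while the tests of opposite early changes were set before their result.

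Some groups moved at single times that the windows average out. Histone genes in the heat series stood at -1.38 from their start at 60 min, with a mean change of -0.08 at 30 min and 0.05 at 2 h, while the control was at -0.08 and the cold series at 0.00 at 60 min. The histone list did not pass in heat early (adjusted p = 0.055). S phase genes in heat stood at -1.16 at 30 min and 0.22 at 2 h. Hexose transporter genes in heat lay between 0.42 and 0.75 above their start from 15 min to 8 h, where the control stayed between 0.10 and 0.25, and this list did not pass in heat early or late.

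In the cold series glucose-repressed genes climbed step by step, with mean changes of 0.57 at 2 h, 1.09 at 4 h, 1.41 at 8 h and 1.51 at 24 h, whereas in the control the mean was 0.25 at 8 h and 2.48 at 24 h. Mating genes parted at 24 h, with a mean change of 1.09 in cold, -1.32 in heat and -0.66 in the control. Chaperones at 24 h stood above their start in heat (1.47) and in the control (1.01), and less so in cold (0.27). Each of these is the mean of a list on 1 array per time, without a test.

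Heat and cold may move the same genes in opposite directions early on. Across the 5449 genes the early changes, each from its own 0 min array, correlated at r = -0.663 (rho = -0.586), and 3803 genes (69.8%) had opposite signs. Genes are not independent replicates, and the series share no array in this measure. The members of the stress and ribosome biogenesis lists alone do not carry the opposition, since r was -0.617 over the 5313 genes outside them. These lists hold 41 and 95 genes, and genes of the same kind outside them, such as NAN1 and CGR1, stayed in. The value therefore cannot decide whether the opposition reaches beyond stress and ribosome biogenesis genes in general. By time, r went from -0.72 at 15 min through -0.65 at 30 min, -0.49 at 60 min and -0.08 at 2 h to 0.15, 0.27 and 0.45 at 4, 8 and 24 h, and was 0.374 over the late window. At 24 h all 3 series had moved from their start, so the positive late values may in part be a shared change of culture, for which the growth stage value of 1.51 is the only test made here.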
